A study of Papio anubis with 18 samples.

How the data were processed

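RNA-seq libraries of 4 Papio anubis cell lines, 2 ESC lines (B4, B15) and 2 iPSC lines (160-2, M14939#3), were analysed, with 3 libraries per line. Per the labels' protocols, cells were grown on feeder cells in a medium for human pluripotent cells, and libraries were made with the SMART-Seq v4 kit for low amounts of RNA followed by Nextera XT, which do not mark the strand. The authors deposited a table of raw read counts per gene, with 29475 Ensembl gene identifiers and 18 columns, each a library on a lane. Per the submitters' processing notes, featureCounts and edgeR were used, without role or version. The aligner, genome build and annotation release are not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical copies of a gene, can therefore not be told apart in these counts. RNA of the feeder cells could not be assessed, because the identifiers have no names here.

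Each column was assigned to a library by its name, which is given in the sample description. The lanes of a library were summed, which gave 12 libraries. Before summing, lanes were compared by an index that is 1 for pure counting noise, over genes with at least 20 counts in the pair: it was 1.23 to 2.27 between lanes of a library (6 pairs) and 30.0 to 262 between libraries of a line (12 pairs). Total counts were 62634176, 20614388 and 24106215 for replicates 1 to 3 of ESC B15, 28389859, 12049925 and 34125452 for ESC B4, 38783715, 41215151 and 30413192 for iPSC 160-2, and 23006622, 24517942 and 22685551 for iPSC M14939#3. TMM factors were 0.779 for ESC B15 replicate 2 and 0.949 to 1.08 for the others. No count was recorded in any library for 1006 identifiers.

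Libraries of 1 line are separate samples in the labels, which do not say whether they came from separate cultures, so p-values from the 12 libraries measure the spread between libraries of a line, and that spread may be partly technical. Counting intervals and statements on 0 counts cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

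The reference table of baboon genes used here (39274 genes of the assembly Panubis1.0) holds no Ensembl identifiers, and 0 identifiers of the count table could be matched to a symbol. Gene lists fixed beforehand by symbol were therefore not tested, and marker genes are not reported. The rule for genes named in the text was fixed before the data were examined, as were the groups, tests, covariates and most alternatives. For the cell types it takes genes with adjusted p under 0.05 whose 4 differences between an iPSC and an ESC line have the same sign and are at least 1 on the log2 scale, ranked by the smallest of the 4. For lines of a type it takes genes with adjusted p under 0.05, mean log2 CPM of at least 2 and no overlap between the libraries of the lines, ranked by fold change. The rule asked for genes with a symbol; without symbols this part was dropped, and the first 2 genes in each direction are given by identifier. ENSPANG00000036144 and ENSPANG00000035794, from the comparison of line sums, lie outside the rule and were chosen after their values were seen. ENSPANG00000006115, at rank 3 of the genes lower in iPSC under the rule, was added to complete the genes called lower on line sums.

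Tests used edgeR 4.0.16 in R 4.3.3 with TMM normalization, filterByExpr and the robust quasi-likelihood fit, and an adjusted p (Benjamini-Hochberg) under 0.05. A single fit of the 12 libraries (17106 genes, 7 residual degrees of freedom) had the line and the library set as terms. It gave the contrast of the mean of the iPSC lines with the mean of the ESC lines, the pairs of lines, the other ways to part the 4 lines, and the library set. A second fit summed counts per line, 2 lines against 2, with the cell type as its only term. Another fit used the line and log2 of the number after the letter p. Log2 differences are edgeR's values, which are shrunken towards 0. Each SE is the absolute unshrunken difference divided by the square root of the F statistic of its test. Intervals of 95% for log2 differences use this SE around the unshrunken difference, so they need not be centred on the printed value. CPM values are counts scaled to a common library total, from each library's own total, and log2 CPM used TMM and a prior count of 2. Variance shares are medians over genes of shares of the sum of squares, set beside the medians of the beta distributions that normally distributed values without structure would follow. Scaled ratios of counts are sums over libraries divided by TMM-scaled totals, with an exact conditional binomial interval of 95%.

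The code was tested on simulated counts drawn from the real means, library sizes and dispersions of 17106 genes, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 28% of 2-fold and 87% of 4-fold changes for the mean of the lines, 7% and 72% for the ESC pair, 9% and 72% for the iPSC pair, 35% and 88% for the library set, 44% and 94% for the slope with the p number, and 3% and 61% for line sums. Unchanged genes called in these simulations numbered 4, 10, 4, 8, 5 and 12 in the same order. Calls from line sums and the ESC pair thus held more false calls there than the threshold of 0.05 implies, and the library set slightly more. Each comparison was simulated in a single draw, which does not rank the comparisons by their false calls. Overlaps of gene lists, a comparison added after the data were seen, were set beside the product of the list sizes divided by the number of genes tested, and beside 20 draws of simulated counts without any change. Since at most 2 genes passed the threshold for the cell types in such a draw, each list of a draw took as many genes of lowest p as the real list held. Alternatives were median-of-ratios size factors, no filter, DESeq2 1.42.0, no term for the library set, the replicate number as a block, the first lane of each library alone, libraries thinned to 12049925 counts, each library set alone, limma 3.58.1 with the line as a random block, and leaving out each library or line.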

Results

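Gene expression was profiled in embryonic stem cells (ESC) and induced pluripotent stem cells (iPSC) of the olive baboon, Papio anubis. ESC lines are derived from embryos, and iPSC lines from somatic cells that were reprogrammed to a pluripotent state. The ESC lines were B4 and B15 and the iPSC lines were 160-2 and M14939#3. All 4 lines were grown on feeder cells, and 3 RNA-seq libraries were counted for each line, 12 in total. The total count per library ranged from 12049925 in ESC B4 replicate 2 to 62634176 in ESC B15 replicate 1. Of these libraries, 6 were run on 2 lanes (4 ESC and 2 iPSC) and 6 on 1 lane (2 ESC and 4 iPSC). Genes are given by their Ensembl identifiers, since the files do not pair them with names.

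The 12 transcriptomes were close to one another, and libraries of different cell types correlated about as well as libraries of different lines of a single type. Correlation of log2 CPM (counts scaled to the library total) across genes, which are not independent replicates, averaged 0.962 ± 0.0097 (SD, 12 pairs) between libraries of the same line. It averaged 0.951 ± 0.010 (SD, 18 pairs) between different lines of the same cell type and 0.950 ± 0.012 (SD, 36 pairs) between cell types. Grouping the lines by cell type did not give a higher correlation within groups than between them beyond other groupings of the lines (exact permutation test over the 3 ways to split the lines, p = 0.667; the smallest p this design allows is 0.333). The median over genes of the share of variance was 6.95% between cell types and 23.1% between lines of a type, against 4.67% and 14.3% for normally distributed values without structure. The library set, meaning the libraries run on 1 or on 2 lanes, had a median share of 8.05% within lines, against 4.67% without structure. With sums of squares pooled over genes, a summary added after the data were seen, the 3 shares were 14.7%, 27.8% and 17.4%, against 9.09%, 18.2% and 9.09%. Values without structure treat the 12 libraries as independent. Differences between lines alone would also raise the share between cell types. Its excess over these values therefore does not show a difference between cell types beyond that between lines. The library with the highest correlation came from the same set for 11 of the 12 libraries, from the same cell type for 9 and from the same line for 7. The 9 include the 7. A line has 3 libraries, while a cell type and a library set have 6 each, so these counts cannot be set directly beside each other. Between cell types, the correlation averaged 0.958 for libraries of the same set and 0.943 for libraries of different sets.

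**Figure D1:**
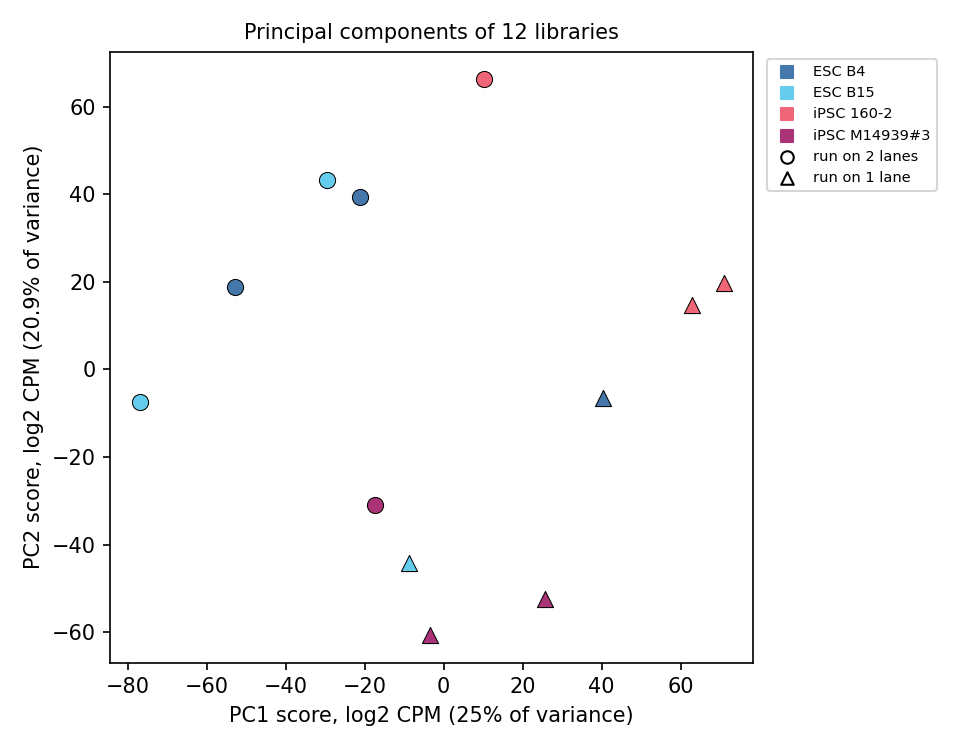
Scores of the 12 libraries on the first and second principal components of log2 CPM (25.01% and 20.9% of the variance), with colour for the cell line, circles for libraries run on 2 lanes and triangles for libraries run on 1 lane. Libraries of different cell types lie among each other, and in each line the libraries run on 1 lane have higher PC1 scores than those run on 2 lanes.

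The study set iPSC beside ESC. First in the ranking fixed for this comparison was ENSPANG00000035342, at 549 ± 139 CPM (SD, n = 6) in iPSC libraries and 4.30 ± 0.84 CPM (SD, n = 6) in ESC libraries. Each iPSC library, from 385 to 774 CPM, lay far above each ESC library, from 3.25 to 5.35 CPM. A second gene, ENSPANG00000032997, had 1.21 to 2.56 CPM in the 6 iPSC libraries and at most 0.083 CPM in the 6 ESC libraries. In the other direction, ENSPANG00000014666 had 0.19 to 1.41 CPM in ESC libraries and at most 0.044 CPM in iPSC libraries. ENSPANG00000005169 had 10.03 to 20.4 CPM in 5 ESC libraries, but 0.18 CPM in ESC B4 replicate 1, within the iPSC range of 0.044 to 0.39 CPM.

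In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, comparing the mean of the 2 iPSC lines with the mean of the 2 ESC lines, ENSPANG00000035342 was higher in iPSC by 6.77 on the log2 scale (SE 0.18, adjusted p = 6.97e-12). ENSPANG00000032997 was higher by 5.80 (SE 0.56, adjusted p = 4.83e-05 in the same edgeR test), resting on 334 counts in iPSC and 5 in ESC. Of ENSPANG00000014666, ESC libraries held 126 counts and iPSC libraries 2, an ESC to iPSC ratio of 63.5 after scaling (95% counting interval 17.2 to 530), with an edgeR adjusted p of 1.89e-04. ENSPANG00000005169 fell by 6.11 in iPSC (SE 1.02, edgeR adjusted p = 0.0273). In all, 175 of 17106 tested genes differed, 77 higher and 98 lower in iPSC, and 148 of them by at least 2-fold. Of the 175, 134 had the same direction in all 4 pairs of an iPSC and an ESC line, and 58 (26 higher, 32 lower) were at least 2-fold apart in each pair. Of the 175, 72 also differed between the 2 iPSC lines, 19 between the 2 ESC lines and 18 between the library sets, where independent lists would share 15.5, 0.645 and 11.4. Of the 77 genes higher in iPSC, 10 were higher and 18 lower in M14939#3 than in 160-2 (4.22 and 2.59 for independent lists), and of the 98 lower in iPSC, 21 were higher and 23 lower (5.37 and 3.30). Of the same 77, 4 were higher and 8 lower in ESC B15 than in B4 (0.131 and 0.153 for independent lists), and of the 98, none was higher and 7 were lower (0.166 and 0.195). In the libraries run on 1 lane, 1 of the 77 was higher and 2 lower (1.42 and 3.59 for independent lists), and 3 of the 98 were higher and 12 lower (1.81 and 4.57). The comparisons share libraries and an estimate of the spread, which raises overlaps without any effect. In 20 draws of simulated counts without any change, where lists of the same sizes were made from the genes of lowest p in the edgeR tests, the overlap with the cell type list averaged 30.3 (24 to 38) for the iPSC lines, 4 (2 to 9) for the ESC lines and 39.25 (29 to 48) for the library sets. The 72 and the 19 lay above these ranges and the 18 below. The drawn lists hold unchanged genes of lowest p, while the real lists hold genes past the threshold. These positions therefore do not decide whether the lists overlap more or less than what they share would give. Part of the excess over independent lists may come from what the comparisons share. For 11015 genes (64.4%) the 95% interval of the difference lay within 1 on the log2 scale in both directions. The call for ENSPANG00000005169 was lost when any of 10 of the 12 libraries was left out, with adjusted p from 0.0568 without ESC B15 replicate 1 to 0.135 without iPSC M14939#3 replicate 2 (1.31e-70 to 0.841 over all 22 alternatives).

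The count depended on single libraries: it was 354 without ESC B15 replicate 1, 96 without ESC B15 replicate 3, 89 without ESC B4 replicate 3, 101 without iPSC 160-2 replicate 1, 114 without iPSC 160-2 replicate 3 and 94 without iPSC M14939#3 replicate 2. It was 617 without a filter on low counts and 426 by DESeq2. Each library set alone has 1 library per line for 1 cell type, so its spread comes from the other cell type. Within the libraries run on 1 lane 162 genes differed, within those run on 2 lanes 2 genes differed, and 31 differed when the 12 libraries were compared as 6 against 6 with no term for the line.

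**Figure D2:**
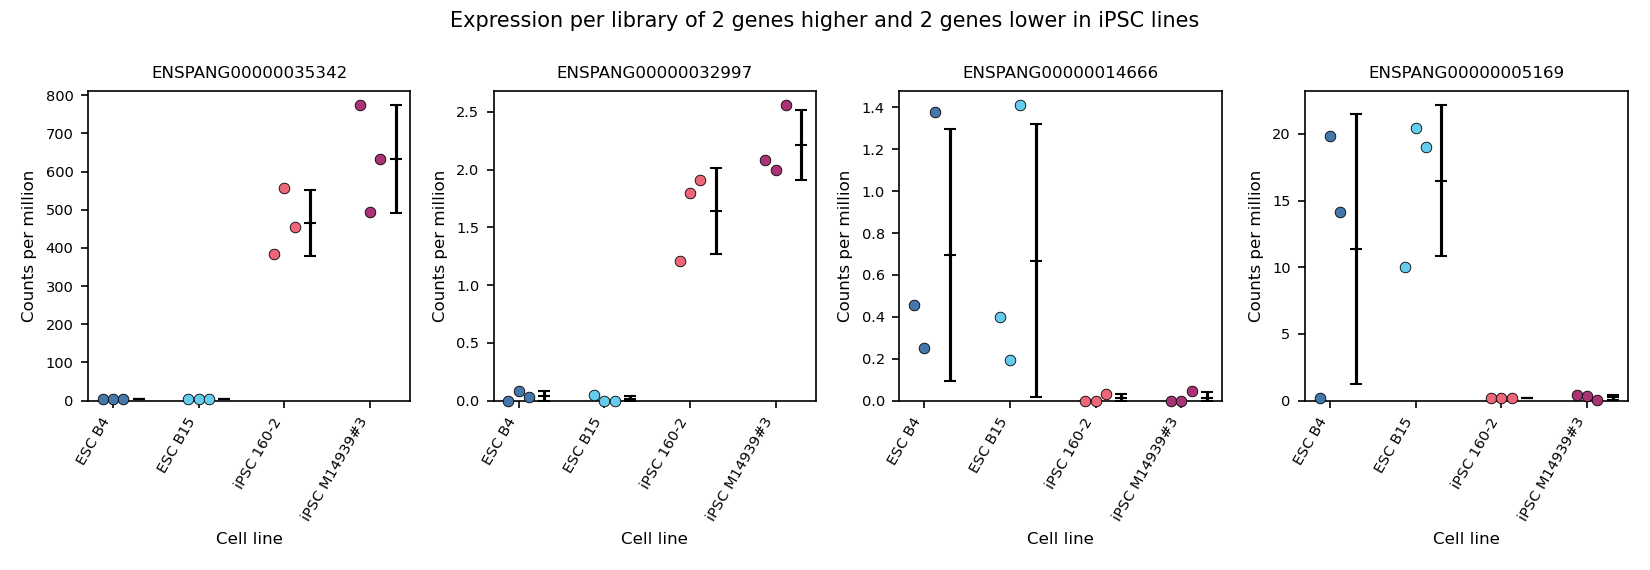
CPM in each library (points, 3 per line) of 2 genes that were higher and 2 that were lower in iPSC lines, with the mean and SD of each line as a bar (n = 3; a bar that would pass below 0 ends there). ENSPANG00000035342 lies between 385 and 774 CPM in iPSC libraries and between 3.25 and 5.35 CPM in ESC libraries, and ENSPANG00000005169 is at 0.18 CPM in ESC B4 replicate 1.

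A statement about cell types rather than about these lines needs the line as the unit, since libraries of a line are not independent of each other. With counts summed per line, 2 iPSC lines against 2 ESC lines, 6 of 19685 genes differed, 2 higher and 4 lower in iPSC, and 772 had an unadjusted p under 0.05. This fit had no term for the library set, and 4 of the ESC but 2 of the iPSC libraries were run on 2 lanes. A difference between the sets can therefore enter it, and deeper libraries weigh more in a sum. ENSPANG00000035342 was again higher, by 6.95 on the log2 scale (SE 0.28, adjusted p = 2.74e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), as was ENSPANG00000032997 (6.04, SE 0.63, edgeR adjusted p = 0.0188). ENSPANG00000005169 fell by 5.79 (SE 0.49, edgeR adjusted p = 0.00791). ENSPANG00000036144 had 1125 counts in ESC libraries, though 0 in ESC B4 replicate 1, and 2 counts in iPSC libraries (edgeR adjusted p = 0.0116). ENSPANG00000035794, another of the 4 called lower, had 1 count in ESC B4 replicate 3. The last of the 4, ENSPANG00000006115, fell by 6.34 (SE 0.70, edgeR adjusted p = 0.0245). It had 5.51 to 27.5 CPM in the ESC libraries and at most 0.43 CPM in the iPSC libraries. How its call moves over the alternatives was not examined. The calls of ENSPANG00000005169 and ENSPANG00000036144 were lost without ESC B4 replicate 3 (edgeR adjusted p 0.0857 and 0.0901) and in limma with the line as a random block (adjusted p 0.9996 for each), with adjusted p from 7.65e-34 and 1.62e-18 up to 0.9996 over all 22 alternatives. That of ENSPANG00000032997 was lost in 4 of the 22, with adjusted p 0.0639 without ESC B15 replicate 1 and 0.0857 without ESC B4 replicate 3 (edgeR; 3.99e-10 to 0.0857 over all 22). Of the 6 genes, 4 were also among the 175. In simulated line sums this test recovered 61% of 4-fold and 3% of 2-fold changes, so differences of 2-fold were mostly not detectable with 2 lines per type. The same simulation also called 12 unchanged genes, more than the threshold of 0.05 implies. Some of the 6 calls may therefore be false. Past the threshold were 1 gene without ESC B4 replicate 3 and 10 without ESC B4 replicate 2. Without a filter on low counts 108 were past it, and 93 by DESeq2.

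The comparison of the 2 ESC lines shows how far lines of a single cell type differ. Both genes named as lower in B15 were close to silent there. ENSPANG00000032398 had 6.64 to 30.4 CPM in the B4 libraries and at most 0.041 CPM in the B15 libraries, which held 2 counts, against 1704 in B4. The scaled B4 to B15 ratio was 1200 (95% counting interval 332 to 9913). ENSPANG00000023193 had 31.4 ± 16.8 CPM (SD, n = 3) in B4 and 0.076 ± 0.024 CPM (SD, n = 3) in B15. ENSPANG00000015002 was higher in B15, at 107 ± 36 CPM against 4.66 ± 1.22 CPM in B4 (SD, n = 3 each), and so was ENSPANG00000023597, at 5.38 ± 4.39 CPM against 0.13 ± 0.10 CPM.

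In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, ENSPANG00000023193 fell by 8.47 on the log2 scale in B15 relative to B4 (SE 0.56, adjusted p = 8.46e-07), and ENSPANG00000015002 was higher by 4.55 (SE 0.30, adjusted p = 8.46e-07). ENSPANG00000023597 was higher in B15 by 5.19 (SE 0.68, edgeR adjusted p = 0.00134). These 4 genes were among 63 that differed, 29 higher and 34 lower in B15, each by at least 2-fold. The count was 196 without ESC B15 replicate 1, 39 without ESC B15 replicate 3, 31 without ESC B4 replicate 1 and 26 without ESC B4 replicate 3. It was 391 without a filter on low counts and 240 by DESeq2.

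The 2 iPSC lines differed in more genes. ENSPANG00000001216 had 44.0 ± 15.8 CPM (SD, n = 3) in M14939#3 and 0.18 ± 0.09 CPM (SD, n = 3) in 160-2. Both ESC lines expressed it, with 30.99 ± 10.5 CPM in B15 and 38.9 ± 10.8 CPM in B4 (SD, n = 3 each). ENSPANG00000016491 was at 56.7 ± 2.6 CPM in M14939#3 and 0.64 ± 0.24 CPM in 160-2, and also differed between the ESC lines, at 110 ± 10 CPM in B4 and 3.44 ± 3.19 CPM in B15 (SD, n = 3 each). ENSPANG00000031605 had 12.4 ± 2.8 CPM in 160-2 and 0.10 ± 0.03 CPM in M14939#3, and ENSPANG00000029305 had 10.7 ± 5.1 CPM in 160-2 and 0.16 ± 0.13 CPM in M14939#3 (SD, n = 3 each).

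By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, ENSPANG00000001216 was higher in M14939#3 than in 160-2 by 7.86 on the log2 scale (SE 0.43, adjusted p = 1.72e-07) and ENSPANG00000016491 by 6.39 (SE 0.63, adjusted p = 1.6e-04). In the same edgeR test ENSPANG00000031605 fell by 6.95 (SE 0.45, adjusted p = 6.3e-07) and ENSPANG00000029305 fell by 6.07 (SE 0.57, adjusted p = 3.13e-05). In all 1513 of 17106 genes differed, 937 higher and 576 lower in M14939#3, and 1126 by at least 2-fold. The ratio of this count to that of the ESC pair was 24.0, and it depended on single libraries: it was 12.6 without ESC B15 replicate 1, 41.5 and 51.9 without replicates 1 and 3 of ESC B4, 15.02, 6.60 and 9.71 without replicates 1, 2 and 3 of iPSC 160-2, and 9.51 and 10.8 without replicates 1 and 2 of iPSC M14939#3. It was 5.98 without a filter on low counts and 10.6 by DESeq2. The count was 2471 without ESC B15 replicate 1, which enters through the shared estimate of the spread, 751, 317 and 505 without replicates 1, 2 and 3 of iPSC 160-2, and 466 and 605 without replicates 1 and 2 of iPSC M14939#3. It was 2339 without a filter on low counts and 2555 by DESeq2. At an unadjusted p under 0.05 by edgeR the pairs lay closer, with 4581 genes for the iPSC lines and 1573 for the ESC lines. Over all tested genes the median absolute difference was 0.456 for the iPSC lines and 0.301 for the ESC lines on the log2 scale.

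The 4 lines can be parted into pairs in 3 ways, of which the cell types are 1. In the fit of the 12 libraries the cell types gave 175 genes. Parting M14939#3 and B15 from 160-2 and B4 gave 1323 genes, 777 higher and 546 lower in the first pair, and parting M14939#3 and B4 from 160-2 and B15 gave 153. Single pairs of an iPSC and an ESC line differed in 159 genes for 160-2 and B4, 587 for 160-2 and B15, 293 for M14939#3 and B4 and 175 for M14939#3 and B15. In at least 1 of the 6 pairs of lines 1853 genes (10.8%) differed. Without a filter on low counts the 1323 and the 153 became 2298 and 521, and by DESeq2 they became 2458 and 406. The 1323 became 3323 without ESC B15 replicate 1, 309 without ESC B15 replicate 3, 454 and 378 without replicates 1 and 3 of ESC B4, 767, 379 and 569 without replicates 1, 2 and 3 of iPSC 160-2, 467 without iPSC M14939#3 replicate 1, 680 with no term for the library set, 1890 within the libraries run on 1 lane and 1 within those run on 2 lanes. The 153 became 98 without iPSC 160-2 replicate 2, 90 within the libraries run on 1 lane and 7 within those run on 2 lanes. Leaving out single libraries moved the 175 too, as given above, and within the libraries run on 2 lanes the cell types gave 2. On line sums the order was different, with 6 genes for the cell types and 0 for each of the other ways by edgeR, where 772 genes for the cell types, 1871 for M14939#3 and B15 against 160-2 and B4, and 581 for M14939#3 and B4 against 160-2 and B15 had an unadjusted p under 0.05.

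**Figure D3:**
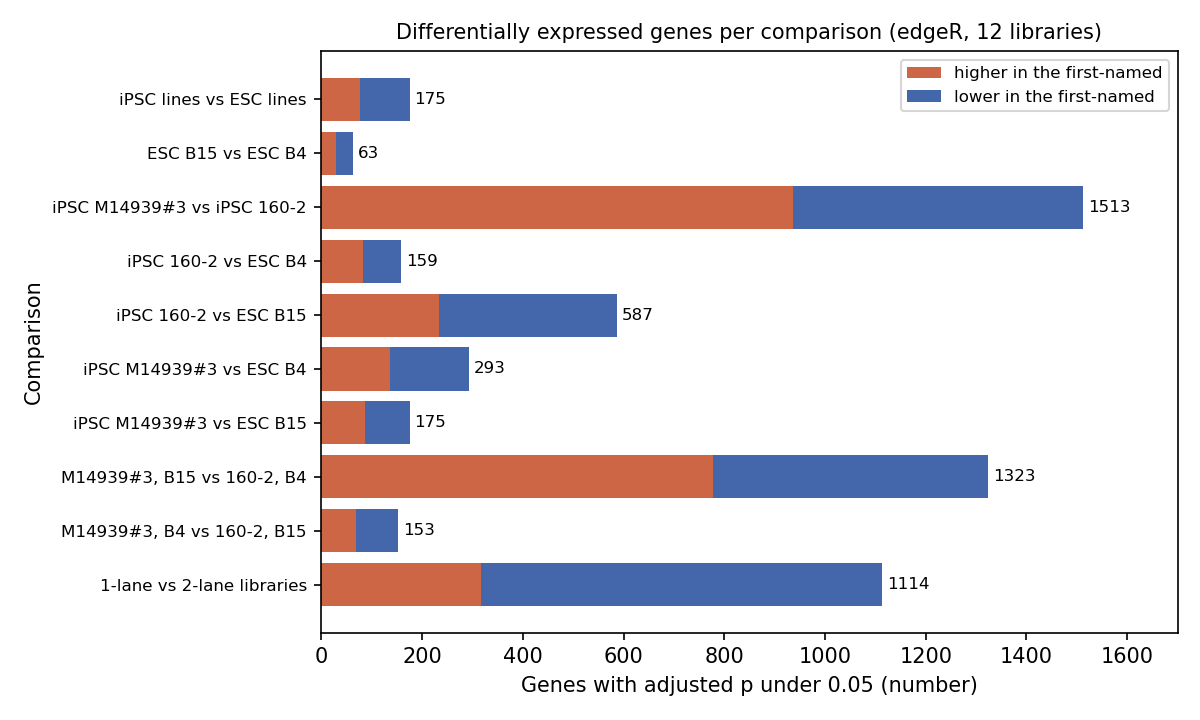
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test on the 12 libraries, for each comparison, parted into genes higher and lower in the first-named group. The bars reach 1513 genes for the 2 iPSC lines, 1323 for M14939#3 and B15 against 160-2 and B4, 1114 for the library sets, 175 for the cell types and 63 for the 2 ESC lines.

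The library sets differed in 1114 genes within lines, 316 higher and 798 lower in the libraries run on 1 lane, in a fit without the replicate number. The sets overlap with that number, as replicate 3 of each line was run on 1 lane. With the replicate number as a block, the sets differed in 40 genes. The counts of 175, 63, 1513, 1323 and 153 genes above come from the fit that included a term for the library set. The 1114 became 552 without ESC B15 replicate 3, 518 without ESC B4 replicate 3 and 457 without iPSC 160-2 replicate 1.

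The sample descriptions give each library a number after the letter p, from 16 to 84, which the labels do not define. Within lines, 89 genes had a slope with log2 of this number in the edgeR test, 13 rising and 76 falling. The higher numbers lie mostly in the libraries run on 1 lane. With a term for the library set 0 genes had a slope by edgeR, with 549 of 17106 at an unadjusted p under 0.05, and 0 did with the number itself in place of its log2, with 2223 at an unadjusted p under 0.05. Each library left out moved the 89 by over 1.5 times: to 15, 177 and 0 without replicates 1 to 3 of ESC B15, to 10, 150 and 173 without those of ESC B4, to 0, 1 and 0 without those of iPSC 160-2, and to 554, 11 and 269 without those of iPSC M14939#3. The 3 counts of 0 stood beside 2115 (ESC B15 replicate 3), 1468 (iPSC 160-2 replicate 1) and 2216 (iPSC 160-2 replicate 3) genes at an unadjusted p under 0.05 by edgeR.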

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

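Thinning for the line pairs and the library set, the first lane alone for the library set, and every alternative for the 2 other ways to part the lines were chosen after the data were seen. Median-of-ratios size factors, the first lane alone and thinned libraries kept each count they were run on within 1.5 times. In the order cell types, ESC pair, iPSC pair, library set, M14939#3 and B15 against 160-2 and B4, and M14939#3 and B4 against 160-2 and B15, counts without a filter were 617, 391, 2339, 1811, 2298 and 521, and counts by DESeq2 were 426, 240, 2555, 1836, 2458 and 406. The slope with the p number gave 324 without a filter and 846 by DESeq2, and line sums gave 108 and 93. Limma with the line as a random block gave 10 between cell types, not 6. Without the term for the library set, the ESC pair gave 39, the iPSC pair 877 and M14939#3 and B15 against 160-2 and B4 gave 680. Libraries run on 2 lanes alone, with 1 library per iPSC line assumed to vary like the ESC libraries, gave 2 for the cell types and 1 and 7 for the 2 other ways to part the lines; those run on 1 lane, with 1 library per ESC line, gave 90 for M14939#3 and B4 against 160-2 and B15. Comparing 6 libraries with 6 gave 31. The slope gave 0 genes with the library set term and 0 with the p number itself (edgeR; 549 and 2223 at an unadjusted p under 0.05). The cause was not tested. Settings on 1 library set use fewer libraries, but both sets hold 6, so this does not account for the gap between the sets. Each set alone takes its spread between libraries of a line from 1 cell type.

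Leaving out 1 library gave 89 to 354 genes for the cell types, 26 to 196 for the ESC pair, 317 to 2471 for the iPSC pair, 457 to 1417 for the library set, 309 to 3323 for M14939#3 and B15 against 160-2 and B4, and 98 to 192 for M14939#3 and B4 against 160-2 and B15. For the slope it gave 0 without ESC B15 replicate 3, iPSC 160-2 replicate 1 or iPSC 160-2 replicate 3 (edgeR; 2115, 1468 and 2216 at an unadjusted p under 0.05), and up to 554 without iPSC M14939#3 replicate 1. The libraries behind the ends of these ranges were ESC B4 replicate 3 (89, 26), ESC B15 replicate 1 (354, 196, 2471, 3323, 192), iPSC 160-2 replicate 2 (317, 98), iPSC 160-2 replicate 1 (457), ESC B15 replicate 2 (1417) and ESC B15 replicate 3 (309). Line sums gave 1 gene without ESC B4 replicate 3 and 236 without the line iPSC 160-2; without B15, B4 or M14939#3 they gave 22, 73 and 98.

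With the replicate block, the cell types gave 129 genes, the ESC pair 51, the iPSC pair 1376 and the library set 40 in place of 1114, fewer than the cell types; each replicate 3 was run on 1 lane. Libraries with the same number in different lines had deviations correlated at -0.22 to 0.44 (mean 0.127, against -0.064 for other numbers), and 8 of 12 libraries correlated best with their own number. As 11 of 18 pairs and not all were above 0.1, the number was not taken as a pairing. Block fits on line sums and the gene lists were not run.

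ENSPANG00000035342 kept its direction and its call in all 22 alternatives of each cell type test. In the mean of the lines ENSPANG00000032997 and ENSPANG00000014666 lost theirs in 1 of 22 and 1 of 20 alternatives, within libraries run on 2 lanes (ENSPANG00000014666 had no value in thinned libraries or 6 against 6), and ENSPANG00000005169 in 12 of 22 alternatives (adjusted p 1.31e-70 to 0.841). On line sums, ENSPANG00000032997 lost its call in 4 of 22 alternatives (adjusted p up to 0.0857), and ENSPANG00000005169 and ENSPANG00000036144 in 2 each, limma and without ESC B4 replicate 3. The 8 genes named for line pairs kept their calls in all 19 alternatives. Depth limits ENSPANG00000014666 (2 iPSC counts).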

Other observations

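The tests of the time in culture, of genes switching between libraries of a line, of genes near silent in whole lines and of neighbouring table rows were chosen only after the results were seen. Some genes were on in some lines and near silent in others: 4 genes had at least 5 CPM in each library of some lines and under 0.3 CPM in each library of the rest. Of these, 2 were off in ESC B15 alone, 1 was off in iPSC 160-2 alone and 1 was on in iPSC 160-2 alone; these CPM limits were set after the data were seen. For comparison, 7396 genes had at least 5 CPM in each of the 12 libraries. Switches also occurred within lines, since 31 genes had at least 10 CPM in 1 library and under 0.3 CPM in another of the same line, 9 in B15, 10 in B4, 5 in 160-2 and 10 in M14939#3, with 3 of the 31 doing so in 2 or more lines. The low library was replicate 3 for 7 of the 9 in B15, 5 of the 10 in B4, 4 of the 5 in 160-2 and 8 of the 10 in M14939#3; replicate 3 was run on 1 lane and has the highest p number of its line. ENSPANG00000005169, among the genes lower in iPSC, is of this kind in ESC B4. So are ENSPANG00000036144 (0, 10.04 and 11.99 CPM in ESC B4 replicates 1 to 3) and ENSPANG00000035794 (6.90, 19.2 and 0.029 CPM). Both were called lower in iPSC on line sums, and a sum does not show such a switch.

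Many more genes passed the adjusted threshold between the 2 iPSC lines than between the 2 ESC lines, by a ratio of 24.0, and by 5.98 (no filter) to 51.9 (without ESC B4 replicate 3) over 19 alternatives (12.6 without ESC B15 replicate 1, 41.5 without ESC B4 replicate 1, 15.02, 6.60 and 9.71 without replicates 1, 2 and 3 of iPSC 160-2, and 9.51 and 10.8 without replicates 1 and 2 of iPSC M14939#3). The contrast was smaller at an unadjusted p under 0.05 by edgeR, with 4581 genes for the iPSC pair and 1573 for the ESC pair. The median absolute difference over all tested genes was 0.456 for the iPSC pair and 0.301 for the ESC pair on the log2 scale. With all libraries thinned to the same total the ratio was 27.4, which argues against depth as the cause, and without ESC B15 replicate 2, the library with the lowest TMM factor, it was 32.5. The high p numbers of 160-2 may contribute and stay open: over 1575 genes called in the libraries run on 1 lane (160-2 at 65 and 84), the difference at numbers 17 and 25 was a median 0.656 times as large, with 91.6% in the same direction, but it rests on 1 library of each line, and choosing genes in the first libraries also lowers this ratio. Other splits of the libraries were too few for a share under 0.05, with 1 of 10 as large in each pair: fitted on their own 6 libraries, the iPSC pair gave 1376 genes and at most 0 in another split, and the ESC pair gave 15 and at most 0. A difference between the donors of the lines remains open and untested.

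The ESC line difference and the iPSC line difference shared a direction, B15 and M14939#3 against B4 and 160-2, with a correlation of 0.218 across genes, which are not independent replicates (0.109 without ESC B15 replicate 3 and 0.304 without ESC B15 replicate 1, 0.351 in libraries run on 1 lane and 0.054 in those run on 2 lanes). The correlation was not computed in thinned libraries, so depth was not tested for it. Thinned libraries gave 7.98 times as many genes for this way to part the lines as for the cell types, which argues against depth as the cause of the larger count. This count does not test the shared direction, since it includes the iPSC line difference, which alone gave 1371 genes in thinned libraries. In a fit with the split and the library set, without the line, 2 of 100 splits of the 12 libraries gave as many genes (254, and 438 in a split sharing 10 libraries with it), but most of these splits break up lines, whose libraries are alike, so they do not test a grouping of whole lines. Variation that also occurs among libraries of a line cannot be told apart from a shared line difference, since removing its first 3 components left a correlation of 0.171, but 0.053 without ESC B15 replicate 3 and 0.299 without ESC B15 replicate 1. Of whole lines there are 3 splits, too few for a share under 0.05, and on line sums this one gave 0 genes by edgeR, with 1871 at an unadjusted p under 0.05.

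Libraries run on 1 and on 2 lanes differed in 1114 genes (552, 518 and 457 without ESC B15 replicate 3, ESC B4 replicate 3 and iPSC 160-2 replicate 1). With the first lane alone the count was 1065 and with thinned libraries 985, against the second lane's reads or depth as its cause. None of the other drawn splits came close, as the sets themselves were the 1 of 50 as large and the highest other gave 1. Such a count was thus rare among the drawn splits in this fit, which has no term for the replicate number. The draws did not have to part each line, as the sets do, and they do not part the sets from the replicate number. With that number as a block the sets gave 40 genes. If the p number counts passages, time in culture alone would leave at most a small difference, turned around, in M14939#3 between numbers 16 (1 lane) and 17 (2 lanes). The correlation of that difference with the set difference of the other 3 lines was 0.247 (0.128 to 0.254 with single lines). This rests on 1 library against 1 with adjacent numbers, so time in culture stays open. A difference in preparation or sequencing of the sets, which was not tested, stays open too. In the column names, the number after the letter S is lower in every library run on 2 lanes than in any run on 1 lane. The labels do not define this number.

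For the cell types, the same fit without the line gave 31 genes, and 3 of 100 splits gave as many, with 438 in the highest other. The 3 splits by whole lines, which were included on purpose, gave 31, 254 and 22 genes, which points to a structure of the samples by line, so splits that break up lines do not test the cell types. On line sums the cell types gave 6 genes and the highest of the other splits 0 (edgeR, with 1871 and 581 at an unadjusted p under 0.05 in the other 2, against 772), which is 1 of 3 splits and too few for a share under 0.05. The difference between cell types did not differ detectably between the library sets, with 0 genes by edgeR for the interaction and 639 of 17106 at an unadjusted p under 0.05.

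Called genes lay next to each other in the deposited table more often than in shuffled orders. Between the iPSC lines 109 pairs of consecutive tested genes were both called in the same direction, against a mean of 70.4 and at most 96 in 1000 shuffled orders; between cell types there were 11 against at most 5, between the ESC lines 4 against at most 2 and between library sets 75 against at most 68 (permutation p = 0.001 for each, the smallest that 1000 shuffles can give). Whether the order of the table follows the chromosomes is not stated in the sources used here. Over runs of 100 tested genes, the largest median shift of a line from the mean of the lines was 0.33 on the log2 scale, in iPSC 160-2, against at most 0.22 in 100 shuffled orders. For single libraries the largest was 0.57, in ESC B15 replicate 2, the library with the lowest TMM factor; no shuffled orders were run for these.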
